A study of Mus musculus with 24 samples.

How the data were processed

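Gene expression was measured on Affymetrix microarrays in left ventricular tissue from mice of 4 genotypes at 4 and 12 months of age. There were 24 arrays in 8 groups of 3, and the titles call the arrays of a group biological replicates. Per the labels' protocols, the tissue was frozen in liquid nitrogen, total RNA was isolated with Trizol and cleaned on a column, and biotin-labelled cRNA was made from 300 ng of total RNA. The deposited values are log2 expression values, 1 per probe set and array, made by the authors with RMA per the submitters' processing notes. RMA corrects the background, sets the arrays to 1 distribution and summarises the probes of a probe set. Its version and settings, and the genome build behind the probe sets, are not given in the sources used here. The deposited table held 35557 probe sets with values from 1.2073 to 14.5274, and array medians lay between 5.777 and 5.901. The largest difference between arrays at the same rank was 0.4765 on the log2 scale. An array has no read depth, so the number of arrays limits the precision.

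Groups were taken from the sample titles. The title, the description and the age label of the Tm180/PLB KO array of replicate 2 at 4 months give 4 months, whereas its source name gives 12, and it was kept at 4 months. The labels do not give the sex of the mice. Arrays of a group correlated at 0.9615 to 0.9879 over the 15918 genes left by the dim filter described below, and 0 pairs of arrays held identical values.

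Probe sets were named from the platform annotation supplied with the series. It gave 1 gene symbol for 21789 probe sets, several for 1621 and none for 12147, and no gene was named from a probe set without exactly 1 symbol. Of the 21789, 21698 were matched by Entrez number to a RefSeq gene of the GRCm38.p6 assembly, which was used for current symbols and for which genes are neighbours. The named probe sets covered 19938 genes, and for the 999 genes with more than 1 probe set the one with the highest mean was used. Genes had to exceed 4.83, the 25th percentile of these values, on at least 3 arrays, which left 15918.

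The main model was a limma fit (limma 3.58.1, R 4.3.3) of the 8 group means to all 24 arrays, with an empirical Bayes variance prior without trend and 16 residual degrees of freedom. Each of 19 contrasts was tested over the 15918 genes with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. All adjusted p-values of genes are limma's. Changes are log2 differences with their standard error (SE), and group levels are means with the SD over 3 arrays. The 36 gene lists of pathways and cell type markers were tested with camera in limma at a preset correlation of 0.01, adjusted over 684 tests, and again with an estimated correlation and with fry. The preset passed the threshold in 216 tests, of which 11 also passed with an estimated correlation. List tests of the main effects, added later, were adjusted separately over those effects alone. Single values were compared by two-sided exact permutation tests, which cannot go below 0.1 for 3 arrays against 3. The groups, contrasts, lists, filters and the rule for named genes were fixed before the data were examined.

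Named genes followed that rule. Pln and Tpm1 were always given. In each genotype contrast, the 10 highest and 10 lowest called genes were taken whose 3 arrays of one group all lay above the 3 of the other, a separation that chance gives 10% of genes. For age contrasts and interactions the 5 highest and 5 lowest called genes were taken. Predicted and clone-named genes were counted and not named. Up to 4 called members of each list were added, or the values of 2 members where none was called.

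The replicate numbers were examined as possible pairs. The letter of each sample's description code went with the replicate number. The number of the code went with the group: each of the 8 groups had a single number, 1 to 4 at 12 months and 5 to 8 at 4 months. The labels do not explain the code, so an effect of its number could not be told apart from genotype or age. Same-numbered arrays of different groups deviated from their group means together, with a median correlation over genes of 0.44, against -0.238 for differently numbered arrays. Deviations from a group mean cancel within the group, so the negative value follows largely from the positive one and is no separate baseline. All same-numbered pairs exceeded a correlation of 0.1 in 11 of the 19 contrasts, and in the report the count from a model with the replicate number as a block is printed beside these alone. The closing section also gives it for other contrasts, whose numbers were not shown to pair, and for the main effects. Replicate number explained 77.3% of the first principal component, which held 27.2% of the variance.

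Alternatives were the replicate block, no dim filter, a filter at the 50th percentile (6.23, 10944 genes), a trended robust variance prior, a fit to the compared groups alone, median centring, a second quantile normalization, the mean of a gene's probe sets, array weights, and leaving out each array. Covariates for Y-linked genes, for the atrial genes Myl7, Myl4 and Sln and for immediate-early genes were added after seeing the data, as were the main effects of Tm180, PLB KO and age over all arrays, tests of the fetal list without its atrial markers and with these covariates, of the calcium handling list without Pln, and of Slc16a13 and Bcl6b by age, leaving out each knockout array for the residual Pln signal, tests of the genes called in Tm180 at the other age, and 200 simulations of unchanged groups with the replicate numbers kept. The model was tested on simulated data for Tm180 against NTG at 4 months over 15918 genes, of which 200 were changed. It recovered 49.3% of 67 genes changed 1.5-fold, 83.6% of 67 changed 2-fold and 100% of 66 changed 4-fold, and called 4 unchanged genes. The simulated noise was independent between genes and between arrays, without the shared deviations of same-numbered arrays. These figures may therefore not hold for the real arrays. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.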

Results

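The series asked how left ventricular gene expression changes with age in a mouse model of familial hypertrophic cardiomyopathy, and in that model without phospholamban. Tm180 mice carry a mutant α-tropomyosin transgene. PLB KO mice lack phospholamban, the small membrane protein that restrains the calcium pump of the sarcoplasmic reticulum. Tm180/PLB KO mice have both changes, and nontransgenic (NTG) mice were the controls. Each genotype was measured on 3 arrays at 4 months and 3 at 12 months, which the titles call biological replicates. Over the 24 arrays, 15918 genes passed the filter on dim signals.

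The gene for phospholamban, Pln, separated the genotypes. At 4 months its log2 level was 13.75 ± 0.0651 (SD, n = 3) in NTG and 13.68 ± 0.0499 in Tm180, against 7.89 ± 1.02 in PLB KO and 7.35 ± 0.289 in Tm180/PLB KO. At 12 months it was 13.79 ± 0.0702 in NTG, 13.71 ± 0.151 in Tm180, 6.22 ± 0.504 in PLB KO and 6.33 ± 0.354 in Tm180/PLB KO. Pln fell by 5.86 ± 0.324 (SE) in PLB KO against NTG at 4 months (adjusted p = 7.12e-10), and by 7.57 ± 0.324 at 12 months. The remaining signal was not shown to lie above background, so these falls may be underestimates. On the knockout arrays that signal was higher at 4 months, 7.62 ± 0.733 (SD, n = 6), than at 12 months, 6.27 ± 0.394 (n = 6). Background alone therefore need not set the fall at 4 months. Tpm1, the gene for α-tropomyosin, stood at 12.83 ± 0.0451 in NTG, 13.16 ± 0.0473 in Tm180, 12.80 ± 0.104 in PLB KO and 13.18 ± 0.0814 in Tm180/PLB KO at 4 months. At 12 months Tpm1 was 12.85 ± 0.0635, 13.17 ± 0.0473, 12.77 ± 0.131 and 13.23 ± 0.0379 in the same order. The 3 Tm180 arrays lay above the 3 NTG arrays at both ages, by 0.34 ± 0.0889 (adjusted p = 0.0984) at 4 months and 0.31 ± 0.0889 (adjusted p = 0.132) at 12 months, so Tpm1 was not called in either contrast. Over all arrays, a comparison chosen after seeing the data, Tpm1 was higher by 0.37 ± 0.0444 in the 12 arrays with the transgene than in the 12 without (adjusted p = 3.97e-05). Whether its probes read the transgene, the endogenous gene or both is not given in the sources used here.

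**Figure D1:**
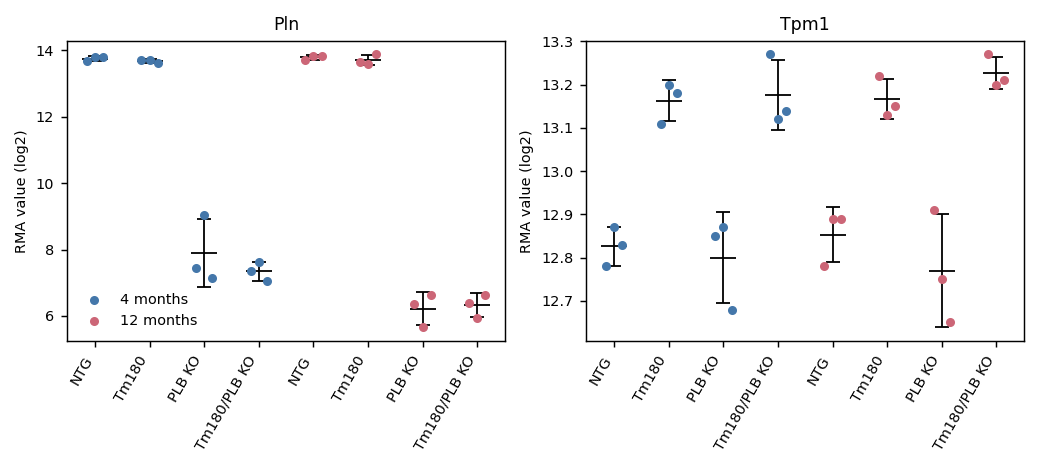
Log2 RMA levels of Pln and Tpm1 on each array of the 8 genotype and age groups, with points for arrays, wide bars for group means and whiskers for the SD (n = 3 per group); the vertical axes do not start at 0. Pln lies near 13.7 in the groups with phospholamban and between 5.66 and 9.05 on the knockout arrays, and Tpm1 lies higher in the groups with the Tm180 transgene.

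The effect of the Tm180 transgene was read from Tm180 against NTG. No group carried a transgene of normal tropomyosin, so the mutation cannot be told apart from the transgene as such. At 4 months the genes that rose most were Thbs4, which encodes a secreted matricellular thrombospondin, by 2.45 ± 0.353 (5.47-fold, adjusted p = 0.00134), and Nppa, the atrial natriuretic peptide gene, by 2.42 ± 0.28 (5.37-fold, adjusted p = 0.00018). Nppa stood at 12.93 ± 0.303 (SD, n = 3) in Tm180 and 10.50 ± 0.556 in NTG. Myh7, the slow β-myosin heavy chain of the fetal ventricle, rose by 1.86 ± 0.207 (3.62-fold), and Postn, the matrix protein periostin, by 1.84 ± 0.304 (3.59-fold). Mylk4, a gene of the myosin light chain kinase family, fell by 1.69 ± 0.229, and Lgi1, Ces1d and the chemokine gene Ppbp fell by 1.81, 1.64 and 1.91.

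In all, 81 genes were called at 4 months, 47 higher and 34 lower, and 65 of them differed at least 1.5-fold. Of 21 measured fetal and hypertrophy marker genes, 4 rose and none fell (8 higher adjusted over the list alone), with a median difference of 0.62 (adjusted p = 0.0233 with an estimated correlation). The 4 were Nppa, Myh7, Mybpc2 (0.97), the fast skeletal myosin-binding protein C, and Xirp2 (0.79), which encodes an actin-binding protein of the intercalated disc. Of 12 activated fibroblast markers, 4 rose: Thbs4, Postn, Cilp (1.64) and Col12a1 (1.16). The list's median difference was 0.91, with 7 higher adjusted over the list alone (adjusted p = 0.0317 with an estimated correlation). Of 56 extracellular matrix genes, 10 rose and none fell, 32 were higher adjusted over the list alone, and the median difference was 0.66 (adjusted p = 0.0526 with an estimated correlation). They included Tgfb2 (1.44) and Tgfb3 (0.89), both ligands of the transforming growth factor β family, Mfap5 (1.20) of the elastic microfibrils, and the proteoglycan gene Dcn (0.50). The named genes that rose also included P3h2 (1.51), a hydroxylase of collagen prolines, Aebp1 (1.19), Pamr1 (1.19), Grk5 (0.72), a kinase of G protein-coupled receptors, and Serping1 (0.74), the complement C1 inhibitor.

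Among 25 cardiac ion channel genes at 4 months, Scn4b, a β subunit of sodium channels, fell by 1.07 and Kcnd2, a channel of the transient outward potassium current, by 0.74. The list had 4 members lower adjusted over the list alone and a median of -0.34 (adjusted p = 0.0906 with an estimated correlation). Slc2a12, a glucose transporter gene, fell by 1.14, Tmod4, a tropomodulin that caps thin filaments, by 1.13, Amy1 by 1.27, Cabcoco1 by 1.06 and Fah by 0.98. None of 31 fatty acid oxidation genes was called, 8 were lower adjusted over the list alone and the median was -0.30 (adjusted p = 0.0992 with an estimated correlation). All 50 genes of oxidative phosphorylation had lower means in Tm180, by a median of -0.20 (adjusted p = 0.107 with an estimated correlation), and 0 of the 50 were called by limma. Over all genes of the contrast, 1129 had an unadjusted p under 0.05. The balance of rises and falls depended on the model. With the replicate number as a block 557 genes were called, 214 higher and 343 lower, and with array weights 776, 321 higher and 455 lower. Those weights leaned on single arrays, with 4.29 for NTG replicate 2 against 0.534 and 0.639 for replicates 1 and 3. In Tm180 replicate 2 had 2.04, against 0.852 and 0.479 for replicates 1 and 3. Median centring gave 48 higher and 48 lower, an immediate-early covariate added after seeing the data 85 and 71, 156 in all, and the 6 compared arrays alone 11 and 2, 13 in all. The count was 23 without NTG replicate 1, 25 without NTG replicate 2, 22 without Tm180 replicate 1 and 34 without Tm180 replicate 2, and 10 of the 28 named genes kept their call whichever array was left out.

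By 12 months Nppa was higher by 2.18 ± 0.28 (4.52-fold, adjusted p = 0.00239) in Tm180 against NTG, and Nppb, the brain natriuretic peptide gene, rose 2.83-fold (adjusted p = 0.00793). Acta1, skeletal α-actin, rose by 1.46, Ryr3, an intracellular calcium release channel, by 1.55 and Ccn2, connective tissue growth factor, by 1.28, and Lbp rose 2.83-fold. Lbp in Tm180 against NTG at 12 months was 0.95 on the log2 scale (adjusted p = 0.369) without Tm180 replicate 2, against 1.502 with it. Ucp3, a mitochondrial carrier of the uncoupling protein family, was lower by 1.92 ± 0.277 (3.79-fold, adjusted p = 0.00413). Its level was 8.58 ± 0.446 (SD, n = 3) in NTG at 12 months and 6.66 ± 0.0779 in NTG at 4 months. In Tm180 it was 6.73 ± 0.349 at 4 months and 6.65 ± 0.534 at 12 months, so the difference lay in a high NTG level at 12 months. Fbp2, muscle fructose bisphosphatase, fell by 1.30, Acsm5 by 1.27, Prps2 by 1.27 and Mylk4 by 1.41.

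The contrast called 127 genes at 12 months, 62 higher and 65 lower, with 110 differing at least 1.5-fold. Of the 21 fetal and hypertrophy marker genes 9 rose and none fell, also 9 adjusted over the list alone, with a median of 0.69 (adjusted p = 0.0256 with an estimated correlation). They included Nppa, Nppb, Acta1 and Myh7 (1.20). Of 56 extracellular matrix genes 8 rose, 27 adjusted over the list alone, with a median of 0.62 (adjusted p = 0.0864 with an estimated correlation), among them Thbs4 (1.51), Postn (1.44), Tgfb2 (1.36) and Ccn2. Thbs4 in Tm180 against NTG at 12 months was 0.88 (adjusted p = 0.267) without Tm180 replicate 2. Thbs4, Postn and Cilp (1.16) were also the 3 of 12 activated fibroblast markers that rose, with 8 higher adjusted over the list alone and a median of 0.86 (adjusted p = 0.0718 with an estimated correlation). Svep1, a large adhesion protein of the matrix, rose by 1.22, the macrophage mannose receptor gene Mrc1 by 0.72, and Nox4, an NADPH oxidase, by 0.95.

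Of 31 fatty acid oxidation genes, Ucp3 and Eci1 (-0.60), an isomerase of unsaturated fatty acyl-CoA, fell at 12 months. In that list 14 were lower adjusted over the list alone, and the median was -0.35 (adjusted p = 0.0728 with an estimated correlation). The 3 cardiac ion channel genes that fell were Kcnj3 (-1.19), a subunit of the acetylcholine-activated potassium channel, Scn4b (-1.03) and Kcnd2 (-0.90), from a list of 25 with 5 lower adjusted over the list alone and a median of -0.34 (adjusted p = 0.0864 with an estimated correlation). Tcap (-0.69), the titin cap of the Z disc, Adra1b (-0.69), an α-adrenergic receptor, Amy1 (-1.42), Cabcoco1 (-1.22), Mrgprh (-1.18) and the ephrin gene Efnb3 (-1.16) also fell. Between the ages, 48 genes were called in the same direction at 4 and 12 months and 0 in opposite directions, where independent lists would share 0.322. Xist, the transcript of the inactive X chromosome, was high on 1 of 3 Tm180 and 2 of 3 NTG arrays at 12 months. With a covariate for Y-linked genes, added after seeing the data, 92 genes were called, 39 higher and 53 lower. Of the 33 named genes 27 kept their call with it. At 12 months the count was 66, 43 and 74 without NTG replicates 1, 2 and 3 and 15 without Tm180 replicate 2. The 6 compared arrays alone gave 0 calls in limma, with 927 genes at an unadjusted p under 0.05 against 1428 in the full model, and 6 of 33 named genes kept their call whichever array was left out.

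**Figure D2:**
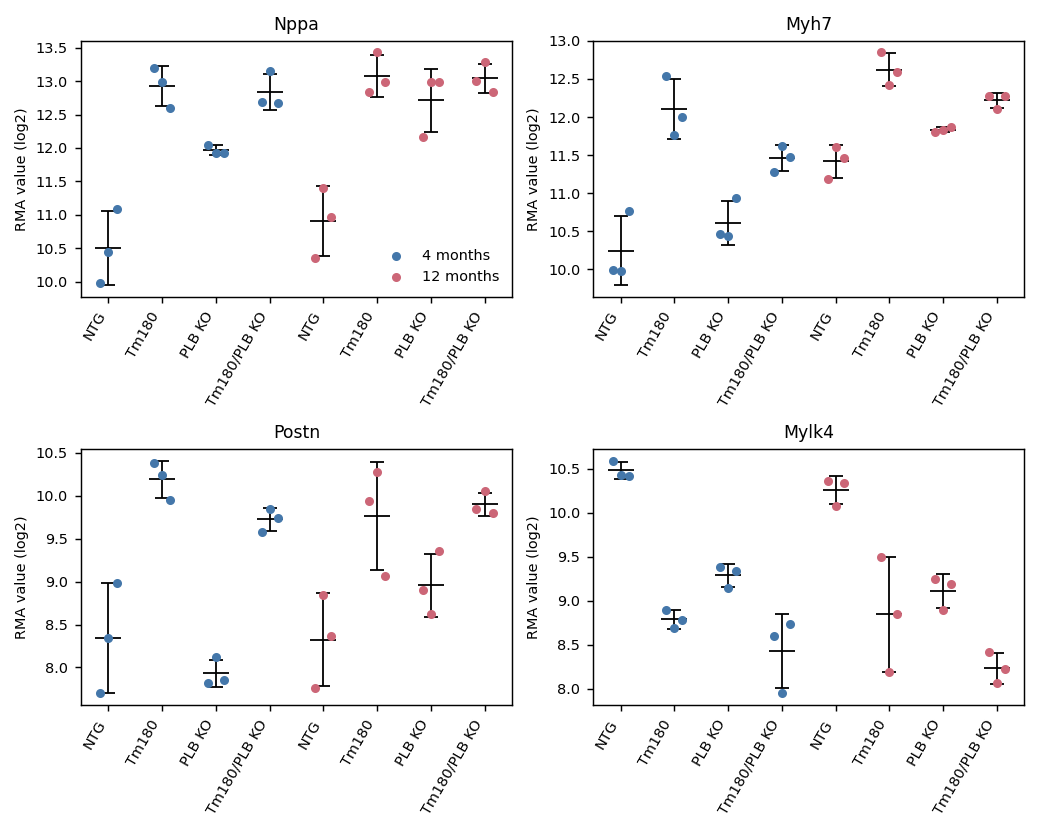
Log2 RMA levels of Nppa, Myh7, Postn and Mylk4 on each array of the 8 genotype and age groups, with points for arrays, wide bars for group means and whiskers for the SD (n = 3 per group); the vertical axes do not start at 0. Nppa lies at 10.50 and 10.90 in NTG at 4 and 12 months and at 12.93 and 13.08 in Tm180, while Mylk4 lies lower in Tm180 than in NTG at both ages.

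PLB KO against NTG measured what the loss of phospholamban did in hearts without the tropomyosin mutation. At 4 months Pln was the only gene called, and 492 genes had an unadjusted p under 0.05. Nppa was 1.46 ± 0.28 higher (adjusted p = 0.162), a difference that passed the threshold with the replicate number as a block (adjusted p = 0.0244). Immediate-early genes, which respond within minutes to stimulation or handling, had a median difference of 1.25 over 24 genes, with 4 higher adjusted over the list alone (adjusted p = 0.139 with an estimated correlation). Values were 2.65 ± 0.978 for Nr4a1 and 2.36 ± 0.726 for Fos, and neither was called. The list's mean level was 8.64 ± 0.402 (SD, n = 3) in PLB KO and 7.36 ± 0.718 in NTG at 4 months. The 21 fetal and hypertrophy marker genes had a median difference of 0.24, with 4 higher adjusted over the list alone (adjusted p = 0.0526 with an estimated correlation). With the block 10 genes were called and with array weights 234, and 2 without NTG replicate 3. The weights were largest for replicate 2 in both groups, at 4.29 in NTG and 2.73 in PLB KO. Xist, the transcript of the inactive X chromosome, was high on 0 of 3 PLB KO arrays and on 2 of 3 NTG arrays at 4 months.

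At 12 months 13 genes were called in PLB KO against NTG, 5 higher and 8 lower, and all 13 differed at least 1.5-fold. Besides Pln, the largest difference was in Nppa, which rose by 1.81 ± 0.28 (3.50-fold, adjusted p = 0.0093). Kctd16, an auxiliary subunit of GABA-B receptors, rose by 1.02, the homeobox gene Dlx5 by 0.88, Xirp2 by 0.69 and Abat, GABA transaminase, by 0.64. Ucp3 fell by 1.49 ± 0.277 (adjusted p = 0.0364), Slc41a3 by 1.14, Lgals4 by 1.11, Acsm5 by 1.06, the axon guidance gene Sema3a by 0.84, Slc25a22, a mitochondrial glutamate carrier, by 0.83 and Tmem47 by 0.78. Of the 21 fetal and hypertrophy marker genes, Nppa and Xirp2 rose, 9 were higher adjusted over the list alone and the median was 0.46 (adjusted p = 0.0129 with an estimated correlation). The list holds the atrial markers Nppa, Myl4 and Myl7, and Myl7 was 2.49 ± 0.843 higher here, though not called. For this contrast the list was not tested without them. All 31 fatty acid oxidation genes had lower means in PLB KO, by a median of -0.32 (adjusted p = 0.0256 with an estimated correlation), with Ucp3 called and 7 lower adjusted over the list alone. Tm180, PLB KO and Tm180/PLB KO were compared with the same 3 NTG arrays of 12 months, so their falls at that age are not independent. Ucp3 stood at 8.58 ± 0.446 (SD, n = 3) on those arrays, against 6.85 ± 0.0972 and 7.09 ± 0.5 in PLB KO at 4 and 12 months.

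Atrial genes stood high in the same PLB KO hearts at 12 months. The mean of Myl7, Myl4 and Sln was 8.26 ± 0.414 (SD, n = 3), against 6.54 ± 1.32 in NTG. The 14 atrial cardiomyocyte markers, which include Nppa, had a median difference of 0.52, with 1 called and, adjusted over the list alone, 7 higher and 1 lower (adjusted p = 0.0805 with an estimated correlation). Xist was high on 3 of 3 PLB KO arrays and 2 of 3 NTG arrays at 12 months. With the atrial genes as a covariate, chosen after seeing the data, 6 of the 13 named genes kept their call, and Nppa was 1.58 ± 0.335 higher (adjusted p = 0.132). The count was 2, 3, 3 and 5 without PLB KO replicate 2, PLB KO replicate 3, NTG replicate 2 and NTG replicate 3, and 1 from the 6 compared arrays alone. Pln was the 1 named gene of 13 that kept its call whichever array was left out, and Nppa in PLB KO against NTG at 12 months lost its call without PLB KO replicate 2 (adjusted p = 0.0903) or PLB KO replicate 3 (adjusted p = 0.0887).

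Tm180/PLB KO against NTG showed what remained when both changes were present. At 4 months Nppa rose by 2.34 ± 0.28 (5.05-fold, adjusted p = 0.000262), Mybpc2 by 1.54 ± 0.193 (2.92-fold) and Myh7 by 1.21 ± 0.207 (2.31-fold). Slc16a13, a monocarboxylate transporter family gene, rose by 1.69 ± 0.31 (adjusted p = 0.0239). Pln fell by 6.41, Mylk4 by 2.05 ± 0.229 (4.14-fold, adjusted p = 0.000129) and Scn4b by 1.44 ± 0.214. The 18 genes called, 9 higher and 9 lower, also included Kctd16 (1.03), Hspa1l (0.92), Gnao1 (0.90), a G protein α subunit, Ramp3 (0.85) and Xirp2 (0.72). Fah (-1.21), Prps2 (-1.16), a phosphoribosyl pyrophosphate synthetase, Lrtm1 (-1.12), Plbd1 (-1.01), Acss1 (-0.63), a mitochondrial acetyl-CoA synthetase, and Tlcd3b (-0.54) fell.

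Nppa, Mybpc2, Myh7 and Xirp2 were the 4 of 21 fetal and hypertrophy marker genes that rose at 4 months in Tm180/PLB KO. In that list 7 were higher adjusted over the list alone, and the median was 0.33 (adjusted p = 0.0256 with an estimated correlation). None of the 56 extracellular matrix genes was called, 7 were higher adjusted over the list alone and the median was 0.39 (adjusted p = 0.165 with an estimated correlation). The 31 fatty acid oxidation genes had 0 called by limma, 10 lower adjusted over the list alone and a median of -0.30 (adjusted p = 0.0864 with an estimated correlation), in a contrast where 1003 genes had an unadjusted p under 0.05. Immediate-early genes again stood higher, at 8.69 ± 0.174 (SD, n = 3) against 7.36 ± 0.718 in NTG, with a median difference of 1.34 over the 24, of which 8 were higher adjusted over the list alone (adjusted p = 0.165 with an estimated correlation). Xist was high on 3 of 3 Tm180/PLB KO arrays and 2 of 3 NTG arrays. With the block 153 genes were called (65 higher and 88 lower), with array weights 309 (149 and 160), with the Y-linked covariate 36 and with the immediate-early covariate 11, both covariates added after seeing the data, and a second quantile normalization gave 8 higher and 13 lower calls. The count was 9 without Tm180/PLB KO replicate 2, 10 without replicate 3 of that group and 8 without NTG replicate 2.

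At 12 months 68 genes were called in Tm180/PLB KO against NTG, 19 higher and 49 lower, with 63 differing at least 1.5-fold. Nppa rose by 2.14 ± 0.28 (4.40-fold, adjusted p = 0.000392), Postn by 1.58 ± 0.304, and Mybpc2 by 1.55 ± 0.193, and Nppb rose 2.83-fold. Kctd16 (1.27), Cilp (1.16), Svep1 (1.05), Gnao1 (0.97), Hspa1l (0.91) and Xirp2 (0.88) rose as well. Pln fell by 7.46, Mylk4 changed by -2.02 ± 0.229 (4.07-fold, adjusted p = 0.000105), and Ucp3 by -1.98 ± 0.277. Fbp2 (-1.56), Prps2 (-1.48), Acsm5 (-1.48), Scn4b (-1.45), Sema3a (-1.28), Mme (-1.24), the peptidase neprilysin, and Cabcoco1 (-1.19) also fell.

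Fatty acid oxidation genes were lower as a group at 12 months in Tm180/PLB KO. All 31 had lower means than in NTG, 4 fell and 21 were lower adjusted over the list alone, with a median of -0.44 (adjusted p = 0.0256 with an estimated correlation). The 4 were Ucp3, the thioesterase gene Acot2 (-1.01), Eci1 (-0.63) and Acads (-0.49), the short-chain acyl-CoA dehydrogenase. The same 3 NTG arrays served the other genotypes at 12 months. Ucp3 was 8.58 ± 0.446 (SD, n = 3) on them, against 6.87 ± 0.271 and 6.60 ± 0.399 in Tm180/PLB KO at 4 and 12 months. Of 21 fetal and hypertrophy marker genes 5 rose, 9 adjusted over the list alone, with a median of 0.30 (adjusted p = 0.0317 with an estimated correlation). Postn and Cilp were the 2 of 56 extracellular matrix genes that rose, with 24 higher adjusted over the list alone and a median of 0.53 (adjusted p = 0.0864 with an estimated correlation). They were also the 2 of 12 activated fibroblast markers that rose, with 5 higher adjusted over the list alone (adjusted p = 0.102 with an estimated correlation). Scn4b was the single called member of 25 cardiac ion channel genes, with 4 lower adjusted over the list alone (adjusted p = 0.0906 with an estimated correlation). The block gave 372 called genes, array weights 116 and the 6 compared arrays alone 12. Without Tm180/PLB KO replicates 1, 2 and 3 the count was 41, 18 and 28, and without NTG replicate 2 it was 24, while 13 of 23 named genes kept their call whichever array was left out.

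**Figure D3:**
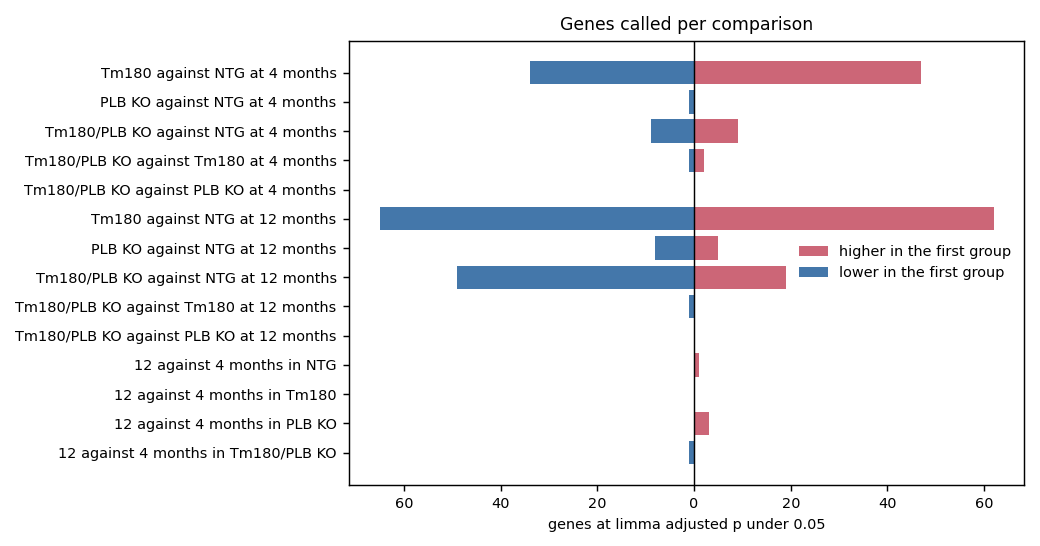
Number of genes called higher and lower by limma (adjusted p under 0.05) in each of the 14 pairwise contrasts of genotype or age. Tm180 against NTG has 47 higher and 34 lower at 4 months and 62 and 65 at 12 months, Tm180/PLB KO against NTG has 9 and 9, then 19 and 49, and the contrasts of Tm180/PLB KO with Tm180 hold at most 3 calls.

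Whether the loss of phospholamban altered the Tm180 heart was asked by comparing Tm180/PLB KO with Tm180. At 4 months 3 genes were called: Pln, which fell by 6.33 ± 0.324, Slc16a13, which rose by 2.04 ± 0.31 (4.11-fold, adjusted p = 0.0148), and Bcl6b, a transcriptional repressor gene beside Slc16a13, which rose by 1.43 ± 0.242 (2.70-fold, adjusted p = 0.0406). Slc16a13 stood at 9.06 ± 0.378 (SD, n = 3) in Tm180/PLB KO, 7.02 ± 0.0872 in Tm180, 8.38 ± 0.348 in PLB KO and 7.37 ± 0.689 in NTG. Thbs4 was -1.80 ± 0.353 (adjusted p = 0.162) and the 12 activated fibroblast markers had a median of -0.45, with 0 called, and 4 lower adjusted over the list alone (adjusted p = 0.0864 with an estimated correlation), in a contrast where limma gave 619 genes with an unadjusted p under 0.05. Immediate-early genes had a median difference of 1.27 over 24, with 2 higher adjusted over the list alone (adjusted p = 0.165 with an estimated correlation). With the immediate-early covariate, added after seeing the data, Bcl6b lost its call at 1.17 ± 0.254 (adjusted p = 0.184). It also lost it with the atrial covariate at 1.40 ± 0.247 (adjusted p = 0.0921) and a second quantile normalization at 1.40 (adjusted p = 0.059), which left 1 higher and 1 lower call, although these estimates stayed close to 1.43. With the block 15 genes were called, with array weights 7, with the Y-linked covariate 6 and from the 6 compared arrays alone 18. The call of Slc16a13 in Tm180/PLB KO against Tm180 at 4 months was lost without Tm180/PLB KO replicate 2 (adjusted p = 0.116), Tm180/PLB KO replicate 3 (0.199), Tm180 replicate 1 (0.0913) or Tm180 replicate 2 (0.129). Bcl6b kept its call without Tm180 replicate 3 and lost it without any other of the 6 arrays, and without Tm180/PLB KO replicate 2, Tm180/PLB KO replicate 3 or Tm180 replicate 2 the count was 1.

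At 12 months Pln was the only gene called in Tm180/PLB KO against Tm180, at -7.39 ± 0.324, and 213 genes had an unadjusted p under 0.05. All 23 macrophage markers had lower means in Tm180/PLB KO, by a median of -0.34 (adjusted p = 0.0864 with an estimated correlation), with 0 called by limma over all genes or adjusted over the list alone. The 19 antigen presentation and complement genes had a median of -0.30 (adjusted p = 0.0992 with an estimated correlation). With the block 1 gene was called, and without Tm180 replicate 1 the count was 5.

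The Tm180 change in hearts without phospholamban was read from Tm180/PLB KO against PLB KO. At 4 months limma called 0 genes, with 436 at an unadjusted p under 0.05, and Postn at 1.79 ± 0.304 and Cilp at 1.12 ± 0.191 had the lowest adjusted p, 0.0509 for both. With the replicate number as a block 22 genes were called, 18 higher and 4 lower, among them Postn (adjusted p = 0.0281) and Cilp (adjusted p = 0.0219). Of the 56 extracellular matrix genes, 23 were higher and 2 lower adjusted over the list alone, with a median of 0.42 (adjusted p = 0.0606 with an estimated correlation). The 12 activated fibroblast markers had a median of 0.42, with 2 higher adjusted over the list alone (adjusted p = 0.0864 with an estimated correlation). Xist was high on 3 of 3 Tm180/PLB KO and 0 of 3 PLB KO arrays, so that sex and genotype cannot be told apart in this contrast. The 4 measured sex-linked genes, Xist and 3 of the Y chromosome, had a median of -3.61, with 1 higher and 3 lower adjusted over the list alone (adjusted p = 0.0864 with an estimated correlation). The count was 1 without Tm180/PLB KO replicate 1, 10 from the 6 compared arrays alone (3 higher and 7 lower), 5 with array weights, 3 with the stricter filter, 3 with the trended robust prior, 2 after a second quantile normalization and 4 with the immediate-early covariate. At 12 months limma called 0 genes, with 451 at an unadjusted p under 0.05, 0 with the block (1299 at an unadjusted p under 0.05), and 1 gene without Tm180/PLB KO replicate 3. The 14 atrial markers had a median of -0.42 in that contrast, with 0 called and 6 lower adjusted over the list alone (adjusted p = 0.0864 with an estimated correlation).

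Genes called in Tm180 at one age were then followed on the arrays of the other age. The group means of those arrays had not been used to choose the genes, but their spread had entered the shared variance estimate. The score was the mean change over these genes, each in the direction called. For the 81 genes called at 4 months, it was 0.76 in Tm180 above NTG at 12 months, 0.35 in PLB KO and 0.66 in Tm180/PLB KO, 86.4% of the Tm180 value. Tm180/PLB KO minus Tm180 was -0.10 (exact permutation p = 0.4, n = 3 against 3), or -0.00626 without Tm180 replicate 2 and -0.16 without Tm180 replicate 3. For the 127 genes called at 12 months, the scores at 4 months were 0.72 in Tm180, 0.20 in PLB KO and 0.51 in Tm180/PLB KO, 71.5% of the Tm180 value. There Tm180/PLB KO minus Tm180 was -0.20 (exact permutation p = 0.1, the smallest that 3 arrays against 3 allow), or -0.13 without Tm180 replicate 1. Tm180/PLB KO minus PLB KO was 0.31 in both cases (exact permutation p = 0.1, n = 3 against 3). Unchanged groups and an NTG group, simulated from the deviations of all 24 arrays from their group means, gave scores centred near 0 with an SD of 0.0806.

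**Figure D4:**
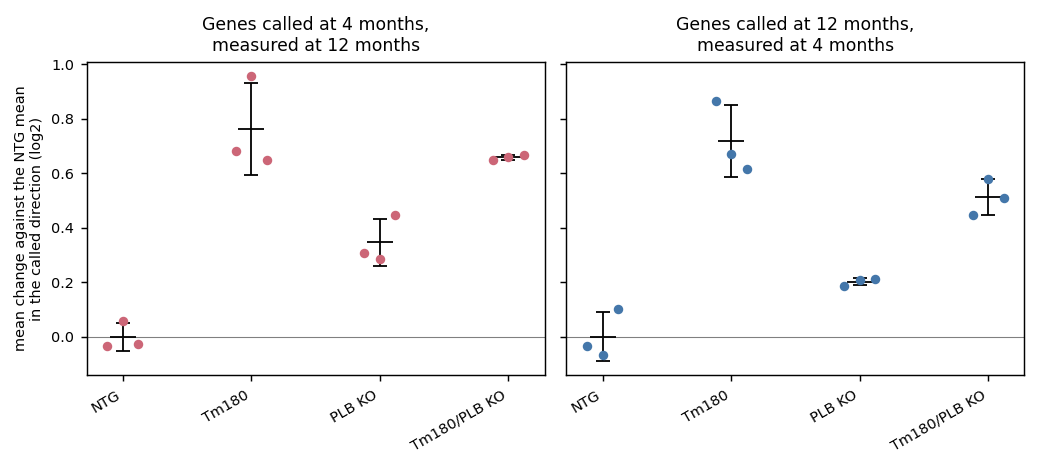
Mean log2 change in the called direction, relative to the NTG mean, on each array of the 4 genotypes, for the genes called in Tm180 at 4 months measured at 12 months (81 genes) and the reverse (127 genes), with points for arrays, wide bars for means and whiskers for the SD (n = 3 per group). Tm180 has means of 0.76 and 0.72, Tm180/PLB KO 0.66 and 0.51 and PLB KO 0.35 and 0.20.

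All 81 genes called in Tm180 at 4 months and all 127 called at 12 months had the same sign in Tm180/PLB KO against NTG, a comparison with the same NTG arrays that chose them. Whether genes moved back towards NTG was asked, after seeing the data, of those called at the other age. Of the 127 genes called at 12 months, 99 were less changed in the called direction in Tm180/PLB KO than in Tm180 at 4 months, and adjusted over these genes alone 13 were called back towards NTG and 1 away from it. Of the 81 called at 4 months, 58 were less changed at 12 months, with 1 called back and 1 away. Tm180 and Tm180/PLB KO shared 11 genes called in the same direction at 4 months, against 0.0437 for independent lists, and 45 at 12 months, against 0.27. At 12 months PLB KO shared 10 with Tm180, against 0.0481, and 10 with Tm180/PLB KO, against 0.0271. Unchanged groups simulated against 1 simulated NTG group shared 0, but groups without a change have hardly any calls to share. That simulation therefore cannot show how far the shared NTG arrays raise the overlap of real calls. The covariance of the Tm180 and Tm180/PLB KO changes over all genes was 0.0241 at 4 months and 0.0378 at 12 months. For PLB KO it was 0.00881 with Tm180 and 0.031 with Tm180/PLB KO at 4 months, and 0.0196 and 0.0216 at 12 months. Unchanged groups simulated with a shared NTG group and the replicate numbers kept, a test added after seeing the data, gave a mean of 0.0131. Their range of -0.00738 to 0.0478 holds all of these values. Part of the overlap may come from the NTG arrays that the contrasts share, which were too few to divide. Across genes, which are not independent replicates, the slope of the Tm180 change without phospholamban on the change with it was 0.372 at 4 months and 0.345 at 12 months. It was 0.221 without NTG replicate 1 and 0.243 without Tm180 replicate 3 at 4 months, and 0.207 without Tm180/PLB KO replicate 2 and 0.222 without NTG replicate 1 at 12 months. Over the genes called at the other age it was 0.467 at 4 months and 0.40 at 12 months. Noise in the change with phospholamban lowers such slopes, so they do not give the share of the Tm180 change that remained.

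The interaction of Tm180 with PLB KO tested whether both changes added up. Limma called 0 genes at 4 months, with 190 at an unadjusted p under 0.05, also 0 with the block (585 at an unadjusted p under 0.05), and 0 at 12 months, with 289. The medians of the 21 fetal and hypertrophy marker genes lay below additivity, at -0.35 at 4 months (adjusted p = 0.0317 with an estimated correlation) and -0.61 at 12 months (adjusted p = 0.0129). Adjusted over the list alone 3 members were lower at 4 months and 8 at 12 months. The list holds the atrial markers Nppa, Myl4 and Myl7, and the mean of Myl7, Myl4 and Sln at 12 months was 8.26 in PLB KO, 6.54 in NTG, 5.88 in Tm180 and 6.21 in Tm180/PLB KO. Without these 3 list members the medians were -0.39 (adjusted p = 0.0528 with an estimated correlation) and -0.52 (adjusted p = 0.044), a test added after seeing the data. Xist was high on 0 of 3 PLB KO and 3 of 3 Tm180/PLB KO arrays at 4 months, and with the Y-linked covariate the medians were -0.25 (adjusted p = 0.141) and -0.61 (adjusted p = 0.0217). At 12 months the call ended with fry once the 3 members were removed (adjusted p = 0.0702), and with an estimated correlation once the atrial covariate was added as well (adjusted p = 0.0818). Values for Nppa were -1.55 ± 0.395 at 4 months and -1.85 ± 0.395 at 12 months, and for Acta1 -1.52 ± 0.48 at 12 months, none of them called over all genes. The count was 1 at 4 months without Tm180 replicate 1 of that age and 3 at 12 months without Tm180 replicate 1 of that age.

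Within a genotype, 12 against 4 months of age called at most 3 genes. In NTG, Ucp3 alone was called and rose by 1.92 ± 0.277 (3.78-fold, adjusted p = 0.0141), with 262 genes at an unadjusted p under 0.05, and 1 gene was called with the block. Its level was 6.66 ± 0.0779 (SD, n = 3) in NTG at 4 months, 8.58 ± 0.446 in NTG at 12 months and between 6.60 and 7.09 as a mean in the other 6 groups. The count was 0 without NTG replicate 2 or 3 of 12 months or replicate 1 or 2 of 4 months, 2 without replicate 3 of 4 months, 0 from the 6 compared arrays alone (limma, 182 at an unadjusted p under 0.05), 11 with array weights, 3 with the immediate-early and 2 with the Y-linked covariate. The 11 epicardial and mesothelial markers had a median of 0.28 in NTG, with 3 higher adjusted over the list alone (adjusted p = 0.0545 with an estimated correlation). In Tm180, limma called 0 genes, with 277 at an unadjusted p under 0.05, 3 without the 12-month replicate 1, 1 without the 4-month replicate 1, and 1 each with the Y-linked and immediate-early covariates.

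In PLB KO, Myh7 rose by 1.22 ± 0.207 with age (adjusted p = 0.0439), Pamr1 by 1.15 and Hebp2 by 0.77, and 889 genes had an unadjusted p under 0.05. The 14 atrial cardiomyocyte markers all had higher means at 12 months, by a median of 0.68 (adjusted p = 0.0317 with an estimated correlation), and 8 were higher adjusted over the list alone. Myl7 was 3.88 ± 0.843 and Myl4 3.11 ± 0.617 higher, and neither was called over all genes. Xist was high on 0 of 3 PLB KO arrays at 4 months and 3 of 3 at 12 months, so that age and sex cannot be told apart there. With the block 12 genes were called, 10 with array weights and 10 from the 6 compared arrays alone, 5 with the stricter filter, 1 without a dim filter, 1 with the Y-linked covariate and 0 in limma with the atrial or the immediate-early covariate (385 and 1069 at an unadjusted p under 0.05). Leaving out any 12-month PLB KO array, replicate 1, 2 or 3, gave 0, and leaving out the 4-month replicate 1 gave 1. In Tm180/PLB KO, Slc16a13 fell by 2.03 ± 0.31 (adjusted p = 0.0325) and was the single call, with 462 genes at an unadjusted p under 0.05. That count was 0 without replicate 1, 2 or 3 of 12 months or replicate 2 or 3 of 4 months, 2 without replicate 1 of 4 months, 41 from the 6 compared arrays alone and 2 with array weights or the atrial covariate.

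Whether age altered a genotype effect was tested by the interactions of age with Tm180, PLB KO and Tm180/PLB KO. Limma called 0 genes in each, with 144, 275 and 199 at an unadjusted p under 0.05. The interaction of age with Tm180 gave 1 gene without the 4-month Tm180 replicate 1. Each of the 3 gave 1 gene with the immediate-early covariate, and the last gave 1 with array weights. In the interaction of age with PLB KO, the 14 atrial markers had a median of 0.56, with 7 higher adjusted over the list alone (adjusted p = 0.0864 with an estimated correlation).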

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

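The interaction tests were planned, and their repeats without the atrial markers or with covariates were chosen only after the data were seen. Of the tests weighing explanations, those of dim probe sets and of sex for the residual Pln signal were chosen before their results were seen, and all other tests of explanations and counts of sample splits only afterwards.

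The fetal marker list and Ucp3 stood out because an effect differed between groups in a test of the interaction. The interaction of Tm180 with PLB KO over the fetal and hypertrophy marker genes had a median of -0.353 over 21 genes at 4 months and -0.61 at 12 months on the log2 scale, and 17 and 18 of the 21 members lay below additivity. With an estimated correlation the adjusted p was 0.0317 at 4 months and 0.0129 at 12 months, and with fry it was 0.121 and 0.0176. The list holds the atrial markers Nppa, Myl4 and Myl7, and sex was unequal between PLB KO and Tm180/PLB KO at 4 months. The 4-month call ended without the 3 atrial markers (median -0.392, adjusted p = 0.0528) and with the Y-linked (-0.245, adjusted p = 0.141) or immediate-early covariate (-0.352, adjusted p = 0.059), within a range of 0.0286 to 0.198 over these repeats. At 12 months the adjusted p was 0.044 without the atrial markers, 0.0217 with the Y-linked covariate, 0.0286 with the atrial covariate and 0.0818 with the atrial covariate and without the atrial markers, where the median was -0.572.

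For Ucp3, with the replicate number as a block the interaction of age with Tm180/PLB KO was -2.19 (adjusted p = 0.0212). Without the block the difference was as large but not called (adjusted p = 0.27), and pairing by number was not shown for this contrast (lowest correlation 0.0247). Ucp3 in age by Tm180/PLB KO interaction was also called with array weights (-2.307, adjusted p = 0.0278) and with the immediate-early covariate (-2.587, adjusted p = 0.0012), within 0.0012 to 1 over the alternatives. Its level went from 6.66 to 8.58 between 4 and 12 months in NTG and from 6.87 to 6.60 in Tm180/PLB KO. A signal also lay in data that no comparison used: of 9057 probe sets tested that do not name exactly 1 gene, 7 were called in at least 1 contrast, and their calls had log2 differences from -2.27 to 1.21.

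Slc16a13 and its chromosomal neighbour Bcl6b were higher in Tm180/PLB KO than in Tm180 at 4 months, and the tables argue against sex as the cause, since Slc16a13 was 2.15 ± 0.296 (SE) with a Y-linked covariate (adjusted p = 0.00456), against 2.04 ± 0.31 without it, and Bcl6b was 1.49 ± 0.244 (adjusted p = 0.0347). A copy gain of the whole segment would have moved the neighbours alike, but the 20 nearest measured genes of GRCm38.p6 had a median of -0.0499 (bootstrap upper bound 0.0529). A strain difference in the surrounding DNA, or a genotype effect, that acts alike at both ages was not excluded. The differences at 12 months were lower, at 0.00825 ± 0.31 for Slc16a13 and 0.182 ± 0.242 for Bcl6b. Both genes were, however, chosen for their large difference at 4 months, which favours a smaller one at 12 months. The change of the difference with age was itself not called (2.03 ± 0.439 and 1.25 ± 0.342, adjusted p = 1 for both). Handling of the tissue was read from immediate-early genes, whose mean at 4 months was 8.69 ± 0.174 (SD, n = 3) in Tm180/PLB KO and 7.45 ± 0.561 in Tm180. With them as a covariate Slc16a13 was still called at 1.44 ± 0.233 (adjusted p = 0.0382, with 0.00456 to 0.199 over the alternatives for Slc16a13 in Tm180/PLB KO against Tm180 at 4 months). A covariate that parts the groups in this way cannot separate handling from genotype, so handling may be part or all of the difference. For Bcl6b handling cannot be told apart from genotype, because the call ended as the estimate went from 1.43 ± 0.242 to 1.17 ± 0.254 (adjusted p = 0.184, with 0.0067 to 0.407 over the alternatives for Bcl6b in Tm180/PLB KO against Tm180 at 4 months). An effect of genotype stays open for both genes, at 4 months alone or at both ages. So does a strain difference in the surrounding DNA, and one that acts at 4 months alone was not tested.

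Nppa stood higher in PLB KO than in NTG at both ages, by 1.46 ± 0.28 (SE) at 4 months (adjusted p = 0.162, 0.0244 with the replicate block) and 1.81 ± 0.28 at 12 months. Atrial tissue in the samples is argued against at 4 months, where the atrial gene Myl7 was -1.26 ± 0.843 and its value plus 2 SE, 0.428, stayed below the Nppa difference. At 12 months it cannot be told apart from an effect of the knockout, since Myl7 was 2.49 ± 0.843 higher and Nppa lost its call with the atrial covariate (1.58 ± 0.335, adjusted p = 0.132; 0.00356 to 0.677 over the alternatives for Nppa in PLB KO against NTG at 12 months), as the estimate fell and its SE grew. Sex alone is argued against, because Nppa was 1.40 ± 0.312 higher at 4 months and 1.84 ± 0.291 at 12 months with the Y-linked covariate, although the adjusted p at 4 months was 0.844. The knockout itself stays open at both ages.

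The residual Pln signal of the knockout arrays was higher at 4 months, 7.62 ± 0.733 (SD, n = 6), than at 12 months, 6.27 ± 0.394 (n = 6; exact permutation p = 0.00216; log2 difference 1.35 ± 0.229 SE, adjusted p = 0.0188). Brightness of dim probe sets is argued against, since 5 of 3481 genes at a similar level, 0.144%, differed as much. Sex is argued against too, as the difference was 1.39 ± 0.246 with the Y-linked covariate (adjusted p = 0.0291). The call ended with the atrial covariate (1.51 ± 0.287, adjusted p = 0.138) and the immediate-early covariate (1.49 ± 0.27, adjusted p = 0.0867) because the SE grew while the estimate did not fall, and it also ended without Tm180/PLB KO replicate 1 (adjusted p = 0.0514) or 2 (0.0588) of 4 months or replicate 1 of 12 months (0.0535). A trace of RNA from hearts with phospholamban could account for it, as the added signal came to 1.06% of their level, or 0.608% without the 4-month PLB KO replicate 2 (log2 difference 1.05 ± 0.152, adjusted p = 0.00358), and age is also open.

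The 6 arrays of a pairwise contrast make 10 splits, the real one included, too few for a share under 0.05. Real counts and the highest of the other splits were 81 and 0, 1 and 1, and 18 and 0 for Tm180, PLB KO and Tm180/PLB KO against NTG at 4 months, and 127 and 0, 13 and 0, and 68 and 0 at 12 months. For Tm180/PLB KO against Tm180 they were 3 and 0 at 4 months and 1 and 7 at 12 months, where 3 of the 10 splits called at least 1 gene. For Tm180/PLB KO against PLB KO they were 0 and 0 at both ages, where all 10 splits reach a count of 0 by construction; limma gave 436 and 451 genes at an unadjusted p under 0.05. The age contrasts gave 1 and 0 in NTG, 0 and 1 in Tm180 (limma, 277 at an unadjusted p under 0.05), 3 and 0 in PLB KO and 1 and 0 in Tm180/PLB KO. In PLB KO against NTG at 4 months, where 2 of 10 splits called 1 gene, and in Tm180/PLB KO against Tm180 at 12 months, the highest other split kept both arrays of a replicate number on the same side, so that it parted fewer pairs than the real one. With the block the real splits called 10 and 1 genes. In the 5 interactions, in which limma called 0 genes and gave 190, 289, 144, 275 and 199 at an unadjusted p under 0.05, all 100 splits drawn reach that count by construction, so the splits say nothing about chance. Their highest other counts were 890 and 577 for Tm180 with PLB KO at 4 and 12 months, and 225, 2 and 14 for age with Tm180, PLB KO and Tm180/PLB KO. Regrouping mixes genotypes, and replicate number explained 50% of the division of the splits with 890 and 577 calls and 16.7% for 225. The cause of the large counts was not tested.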

How the results depend on the processing

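The covariates, the main effects, the repeats for the fetal list and 3 genes followed in contrasts that did not call them were chosen only after the data were seen, and all other tests here were planned. No called gene named for a contrast changed its sign under the alternatives fitted, and no score or slope did. Myl7 in PLB KO against NTG, which was not called, went from -1.26 to 0.14 at 4 months and from 2.49 to -0.05 at 12 months with the atrial covariate, which is made in part of Myl7. The balance of higher and lower calls turned in some models: for Tm180 against NTG from 47 and 34 to 214 and 343 (block) and 321 and 455 (array weights) at 4 months, and from 62 and 65 to 49 and 48 (atrial covariate) at 12 months. For Tm180/PLB KO against Tm180 at 4 months it turned from 2 and 1 to 3 and 4 (array weights) and 1 and 3 (immediate-early covariate). Against PLB KO at 4 months, with 0 calls by limma (436 at an unadjusted p under 0.05), it was 18 and 4 with the block but 3 and 7 from the 6 compared arrays alone. Against NTG at 4 months, even at 9 and 9, it was 8 and 3 with the immediate-early covariate and 65 and 88 with the block. There the stricter filter gave 9 and 15 and the second quantile normalization 8 and 13. The Tm180 main effect went from 336 and 327 to 904 and 998 (block), 375 and 386 (stricter filter), 318 and 395 (median centring), 349 and 360 (second quantile normalization) and 498 and 597 (array weights), and the PLB KO main effect from 17 and 23 to 11 and 6 (immediate-early covariate). Of the counts and scores, 365 values under alternatives set beforehand stayed within 1.5 times (counts) or 1 SD (scores) of the reported value and 88 did not, against 139 and 31 for those added later. Named genes lost their call in 439 cases set beforehand and 204 added later, kept their status in 1964 and 2143, and gained one in 12 and 3. Calls of gene lists were lost in 178 cases with an estimated correlation, in 169 with fry and in 21 with the replicate block. The deposited RMA values give no signal over background for each probe set, so no limit of detection can be stated for dim genes. The cause was not tested for any of the moved values, except that fits to the compared groups alone and fits without an array hold fewer arrays.

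With the replicate block, Tm180, PLB KO and Tm180/PLB KO against NTG called 557, 10 and 153 genes at 4 months and 713, 49 and 372 at 12 months. Tm180/PLB KO against Tm180 and PLB KO called 15 and 22 at 4 months. Age called 12 in PLB KO and 2 in Tm180/PLB KO, the interaction of age with Tm180/PLB KO 1, and the main effects of Tm180, PLB KO and age 1902, 162 and 121. The block ended no call of a single gene in these contrasts and changed no other count by over 1.5 times. Tm180 and PLB KO against NTG at 12 months, age in Tm180 and Tm180/PLB KO, the 12-month interaction of Tm180 with PLB KO and the age interactions are contrasts whose numbers were not shown to pair. A hint from the data is that 24 of 24 arrays correlated best with their own number and 73 of 84 same-numbered pairs exceeded 0.1.

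From the compared groups alone, the limma counts were 13 and 0 (927 at an unadjusted p under 0.05) for Tm180 against NTG at 4 and 12 months, 1 for PLB KO and 12 for Tm180/PLB KO against NTG at 12 months, and 18 and 10 for Tm180/PLB KO against Tm180 and PLB KO at 4 months. Age then called 0 in NTG (182 at an unadjusted p under 0.05), 10 in PLB KO and 41 in Tm180/PLB KO. Array weights gave 776, 234 and 309 for Tm180, PLB KO and Tm180/PLB KO against NTG at 4 months, 116 for the last at 12 months, 7 and 5 for Tm180/PLB KO against Tm180 and PLB KO at 4 months, 11, 10 and 2 for age in NTG, PLB KO and Tm180/PLB KO, 1 for age by Tm180/PLB KO, and 1095, 92 and 73 for the main effects. At 4 months the weight of NTG replicate 2 was 4.29, against 0.534 and 0.639 for replicates 1 and 3. PLB KO replicate 2 had 2.73 and Tm180 replicate 2 had 2.04 at that age. Weighted counts with these groups therefore rest largely on single arrays.

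The immediate-early covariate gave 156 and 11 for Tm180 and Tm180/PLB KO against NTG at 4 months, 4 for Tm180/PLB KO against PLB KO at 4 months, 3, 1 and 0 (limma, 1069 at an unadjusted p under 0.05) for age in NTG, Tm180 and PLB KO, 1 for each age interaction and 17 for the PLB KO main effect. The Y-linked covariate gave 36 and 6 for Tm180/PLB KO against NTG and Tm180 at 4 months, and 2, 1 and 1 for age in NTG, Tm180 and PLB KO. The atrial covariate gave 0 (limma, 385 at an unadjusted p under 0.05) and 2 for age in PLB KO and Tm180/PLB KO. For Tm180/PLB KO against PLB KO at 4 months, the stricter filter and the trended robust prior gave 3 and a second quantile normalization 2; for age in PLB KO the stricter filter gave 5 and no filter 1.

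When genes were chosen with the block, the scores of 12-month genes fell to 0.439, 0.0987 and 0.297 at 4 months in Tm180, PLB KO and Tm180/PLB KO, and those of 4-month genes to 0.476, 0.217 and 0.395 at 12 months. With genes changed at least 1.5-fold, Tm180/PLB KO scored 0.731 at 12 months.

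Without 1 array at a time, counts for Tm180, PLB KO and Tm180/PLB KO against NTG ran from 22 to 81, 1 to 2 and 8 to 20 at 4 months and from 15 to 144, 2 to 17 and 18 to 63 at 12 months. For Tm180/PLB KO against Tm180 they ran from 1 to 4 and 1 to 5 at 4 and 12 months, and against PLB KO from 0 to 1 at both. Age ranged over 0 to 2, 0 to 3, 0 to 3 and 0 to 2 in NTG, Tm180, PLB KO and Tm180/PLB KO, the Tm180 by PLB KO interaction over 0 to 1 and 0 to 3, and age by Tm180 over 0 to 1. The main effects ran from 528 to 734, 26 to 44 and 10 to 32. Slopes of the Tm180 change without phospholamban on the change with it ran from 0.221 to 0.44 at 4 months and from 0.207 to 0.418 at 12 months.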

Other observations

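Main effects over all 24 arrays, 12 against 12, were chosen only after the data were seen, as were the genes named for them, the tests of their splits and the repeats of list tests without some members or with a covariate. Their list tests were adjusted over the 36 lists in the main effects alone, a smaller family than the 684 tests of the contrasts. Adjusted p-values of lists given here are therefore corrected less and cannot be set beside those of the contrasts.

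With both ages and both phospholamban states pooled, 663 genes were called between hearts with and without the Tm180 transgene, 336 higher and 327 lower, of which 91 differed at least 1.5-fold. Beyond Postn (1.51 ± 0.152 SE), Thbs4 (1.46) and Nppa (1.45), 2 genes not named in a single contrast rose here: Prg4 (1.31 ± 0.321), the lubricating proteoglycan lubricin, and Dpysl3 (0.94 ± 0.112). Angpt1, the vascular growth factor angiopoietin 1, fell by 1.04 ± 0.21, Cyp2b10, a cytochrome P450, by 1.04 ± 0.224 and the cytokine gene Il15 by 0.80 ± 0.125. All 20 named genes kept their call whichever array was left out. Of 56 extracellular matrix genes 33 rose and 0 fell, with a median of 0.50 (adjusted p = 0.0233 with an estimated correlation), and 6 of 12 activated fibroblast markers rose, with a median of 0.62 (adjusted p = 0.0233). Markers of fibroblasts in general moved along, with 9 of 18 higher and a median of 0.34 (adjusted p = 0.0685), and 23 macrophage markers had 1 higher and a median of 0.25 (adjusted p = 0.28). Of 31 fatty acid oxidation genes 11 fell, with a median of -0.27 (adjusted p = 0.0369), and 8 of 21 fetal and hypertrophy marker genes rose, with a median of 0.35 (adjusted p = 0.0235, 0.0317 without the atrial markers Nppa, Myl4 and Myl7). Of the 100 splits drawn, 1, the real one, called as many genes and the highest other called 0. The comparison was chosen after seeing the data, and the drawn splits mix hearts with and without the transgene within groups. That widens the spread within groups and lowers their counts, so these splits do not exclude chance. With the replicate number as a block 1902 genes were called, 904 higher and 998 lower.

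Loss of phospholamban, pooled in the same way, called 40 genes, 17 higher and 23 lower. Besides Pln (-6.79 ± 0.162 SE), Sema3a (-0.67), Mylk4 (-0.83) and Lama5 (-0.61), a laminin chain, fell, and Kctd16 (0.68), Mybpc2 (0.67) and Gramd1b (0.56) rose. Of 20 named genes 15 kept their call whichever array was left out and 10 with the immediate-early covariate, where Lama5 lost its call. The 24 immediate-early genes themselves had a median of 0.76 with 1 higher (adjusted p = 0.101 with an estimated correlation). Of the fetal and hypertrophy marker genes 3 rose, with a median of 0.18 (adjusted p = 0.0458), but the call ended without the 3 atrial markers (median 0.10, adjusted p = 0.106). The 14 atrial cardiomyocyte markers themselves had a median of 0.147, with 2 higher and 1 lower (adjusted p = 0.425). Fatty acid oxidation genes had a median of -0.16 with 1 lower (adjusted p = 0.0458), and 38 sarcomere and Z disc genes a median of 0.065 (adjusted p = 0.0233), with 0 called by limma, where 891 of all genes had an unadjusted p under 0.05. The calcium handling genes without Pln numbered 30 and had a median of -0.0239 (adjusted p = 0.16). Chance was not excluded for this count, as 6 of 100 splits called as many. The highest called 4825 genes and had 54.2% of its division explained by replicate number, which points to a structure of the samples, and with that number as a block the real split called 162. Without the 12-month NTG replicate 2 the count was 26, and with the immediate-early covariate 17, 11 higher and 6 lower.

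Age, 12 against 4 months, called 18 genes, 16 higher and 2 lower, among them Myh7 (0.92 ± 0.104), Prkcq (0.85), Efemp1 (0.82), the complement genes C4b (0.81) and C1s1 (0.60) and the clock gene Arntl (0.71). Slc16a13 (-0.85) and Bcl6b (-0.73) were the 2 that fell. Their fall lay mostly in the knockout groups: Slc16a13 changed by -2.03 ± 0.31 in Tm180/PLB KO and -1.14 ± 0.31 in PLB KO, against -0.227 in NTG and 0.00541 in Tm180, and Bcl6b by -1.28 ± 0.242, -1.15 ± 0.242, -0.48 and -0.0283. The difference between groups with and without the knockout, -1.47 ± 0.31 and -0.961 ± 0.242, was not called over all genes (adjusted p = 0.362 and 0.84). Of 12 named genes 7 kept their call whichever array was left out, and Efemp1, C4b and Slc16a13 did not. With the atrial covariate 6 kept it, with the immediate-early covariate 8 and with the Y-linked covariate 11. Efemp1, C4b, Arntl and Slc16a13 lost it with the atrial and Efemp1 and C1s1 with the immediate-early covariate. Of 19 antigen presentation and complement genes 2 rose, with a median of 0.21 (adjusted p = 0.0369 with an estimated correlation). The 11 epicardial and mesothelial markers had a median of 0.24 (adjusted p = 0.0458), and the immediate-early genes one of -0.54 (adjusted p = 0.403). The 14 atrial cardiomyocyte markers had a median of 0.174 (adjusted p = 0.0685 with an estimated correlation). Of 100 splits 1, the real one, called as many and the highest other called 1. These splits mix the ages within groups, which lowers their counts, so chance was not excluded for this count either. The count was 11 without PLB KO replicate 1 or 3 at 12 months. It was 11 as well without Tm180/PLB KO replicate 1 at 4 months or replicate 2 at 12 months. It was also 11 without the 4-month Tm180 replicate 2, 10 without the 12-month NTG replicate 2 and 32 without the 12-month PLB KO replicate 2.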
